A study of Limosilactobacillus fermentum with 2 samples.

How the data were processed

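Total RNA was sequenced from Limosilactobacillus (formerly Lactobacillus) fermentum, a heterofermentative lactic acid bacterium, in 2 strains with 1 library each. Strain GR1009 is described in the labels as a variant of GR1008 with another morphology. Per the labels' protocols, both strains were grown on MRS agar without oxygen at 37 °C for 48 h, cells were taken from the plate, RNA was extracted with a TRIzol-based bacterial kit, rRNA was depleted and cDNA was made with random primers. Random priming does not by itself mark the strand, and the counting strand is not given in the sources used here. The submitters' processing notes name cutadapt 1.9.1, Bowtie2 2.2.6, HTSeq 0.6.1 and DESeq 1.38.0 without their roles or order. The treatment of reads that match several places, and the name of the genome assembly, are not given in the sources used here.

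The deposited table holds 2280 genes with raw read counts per gene for each library, per the file headers. It also holds FPKM values, per the file headers. The deposited FPKM equalled the count divided by the gene's length in the table and by the library's total count. This held to within 0.01 for all 2280 genes in both libraries. FPKM therefore carries no information beyond the counts and gene lengths and was not used further. Genes are called abundant below by their counts, which are not corrected for gene length. The GR1008 columns carry a suffix that the labels do not explain; the name matched no other sample. Gene positions, locus tags, product descriptions and gene symbols (463 of 2280 genes) were taken from the table. Positions are 1-based as the table gives them, on its single chromosome sequence. The table has no strand column, so neighbouring genes are described as runs and not as operons.

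The 73 rRNA and tRNA genes were left out of scaling and comparison because rRNA had been depleted. They held 0.00755% of the counts in GR1008 and 0.00363% in GR1009. Counts of the other genes were scaled by median-of-ratios size factors, the method of DESeq, computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The size factors were 0.840 for GR1008 and 1.19 for GR1009. The log2 ratio of GR1009 over GR1008 was taken on normalized counts with a pseudocount of 0.5. Its 95% interval is the exact conditional binomial (Clopper-Pearson) interval of the 2 counts. Every interval of a ratio or count, and every floor, covers counting error only. An interval of a median over genes comes instead from the ordered log2 ratios and treats genes as independent, which neighbours are not. With 1 library per strain no spread between cultures can be estimated, so no difference has a replicate check and no p-value is given. Genes with at least 10 counts over both libraries were compared (2134 genes). A gene was counted as higher or lower at a ratio of 2 or more. Where a gene had 0 counts, its fold is a bound against a floor of 3 counts in that library.

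A gene was taken as at or near 0 in one library if it had at most 3 counts there and at least 100 in the other. Gene lists were fixed from symbols and product descriptions before the data were examined, as were the size rule, the scaling and the alternatives named as planned. The 28 lists were cell division and cell shape, peptidoglycan synthesis, peptidoglycan hydrolases, polysaccharide synthesis and glycosyltransferases, teichoic acid synthesis and D-alanylation, sortase with surface proteins and adhesins, fatty acid synthesis, purine synthesis, pyrimidine synthesis, arginine metabolism, chaperones and Clp proteases, redox and oxidative stress, ribosomal proteins, aminoacyl-tRNA synthetases, F-type ATP synthase, glycolysis with the phosphoketolase pathway and fermentation ends, citrate, malate, glycerol and mannitol metabolism, sugar uptake and glycoside hydrolysis, peptide and amino acid uptake with peptidases, transposases and insertion elements, prophage, CRISPR-Cas and restriction-modification, competence and DNA uptake, DNA repair and SOS, two-component systems, luxS with bacteriocin and toxin-antitoxin genes, iron-sulfur assembly and metal uptake, and ribosomal and transfer RNA. The lists were matched by words, so a few members fit their list's name only loosely, and some genes belong to more than 1 list. Each list's median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean expression in 10 bins. This percentile describes these 2 libraries and is not a test between strains. Runs were 3 or more adjacent genes that were all higher or all lower by 2-fold, and their number was set beside 1000 shuffles of the calls over the gene order.

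Genes were named by a rule fixed in advance. It took the 15 genes with the highest lower bound and the 15 with the lowest upper bound of the ratio among genes with at least 50 counts in the higher library. It added up to 3 members of each list with the largest ratio in either direction and at least 50 counts, the genes of the 3 longest runs in each direction, up to 10 genes at or near 0, and the 5 most abundant genes of each library. A further set of genes, mostly neighbours and partners of these, is named to complete a group and was chosen after the values were seen. Checks on 2 further patterns, the pyrimidine genes and the IS256 copies, were run and are not reported as weighed patterns; the window with the lowest median was weighed instead, chosen after the values were seen.

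The scaling, the interval and the 2-fold rule were tested on simulated data in 20 simulations of GR1009 against GR1008. These covered 2207 genes, 200 of them changed by known amounts. The intervals covered the true ratio for 95.5% of genes and the scaling factor was off by at most 0.0025 on the log2 scale. Of genes changed by 1.5 on the log2 scale, 99.2% were recovered at 2-fold, and of genes changed by 3, 100%. The changed genes were drawn from those with a geometric mean normalized count of at least 20, with Poisson error alone. Recovery among genes with fewer counts was therefore not measured. Of unchanged genes, 0.606% passed the 2-fold rule by counting error alone. The list percentile was tested on the measured log2 ratios of the 2134 compared genes. Of random lists of 20 genes, 6% fell in the outer 2.5% on either side. Of such lists raised by 0.5 on the log2 scale, 98.5% were found above the upper limit. Alternatives were total count scaling, edgeR 4.0.16 TMM scaling in R 4.3.3, upper quartile scaling, total counts without the 20 most abundant genes, other count filters, a 4-fold rule, a rule on the whole interval, a pseudocount of 5, and other ways of matching random lists. Figures were drawn with matplotlib 3.10.9.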

Results

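Gene expression was compared between L. fermentum GR1008 and its morphotypic variant GR1009, with the question of which genes differ in transcript level between both forms when grown on MRS agar for 48 h. Each strain was represented by 1 library. The GR1008 library held 17604376 gene counts and the GR1009 library 20123186. Of 2280 annotated genes, 2166 had counts in GR1008 and 2182 in GR1009, and the 2134 genes with at least 10 counts in both libraries together were compared. The median gene among these had 1415 counts in GR1008 and 1881.5 in GR1009. Because no strain was sampled more than once, no difference below has a replicate check. The 95% intervals of ratios and counts cover counting error only.

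GR1009 differed from GR1008 above all in a single stretch of 13 neighbouring genes, most of them annotated for polysaccharide synthesis. Together the 13 genes had 19669 counts in GR1008 and 4 in GR1009. Apart from this stretch, genes for ribosomal proteins were higher in the GR1009 library by a median log2 ratio of 0.45. At least 2-fold lower were 5 of 14 pyrimidine synthesis genes, 4 of them adjacent, and a run of Asp23/Gls24 envelope stress genes. With 1 value per run of neighbours the pyrimidine median was only -0.08. Some very abundant single genes, such as those for a Clp ATPase subunit and a P-type ATPase, were also lower. Of 2134 genes, 66 were at least 2-fold higher in GR1009, 121 were at least 2-fold lower, and 1947 (91.2%) lay within 2-fold. The higher genes were mostly of low abundance, with a median of 30.5 counts in GR1009, and 25 of them encoded transposases. The lower genes had a median of 733 counts in GR1008, and 17 of them encoded transposases. For 18 of the higher and 72 of the lower genes the whole counting interval lay beyond 2-fold. Scaling by total counts would move log2 ratios up by 0.31, and scaling by total counts without the 20 most abundant genes by 0.13, or by less for genes with few counts. Under total count scaling 135 genes were at least 2-fold higher and 77 at least 2-fold lower, so the balance between both directions depends on the scaling. Of 27 gene lists with at least 3 compared genes, 5 had medians in the outer 2.5% of matched random lists on either side. Of lists of 20 genes drawn at random from the compared genes, 6% fell there. The fixed lists often hold adjacent genes, so that share need not apply to them. The 10 most abundant genes took 27.6% of the non-ribosomal counts in GR1008 and 21.6% in GR1009.

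**Figure D1:**
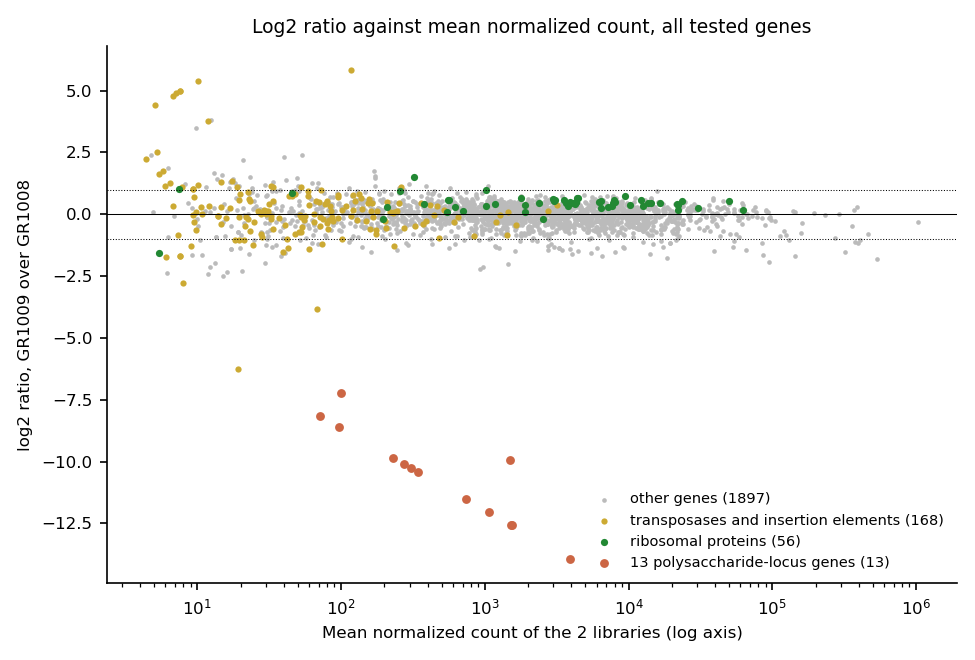
Log2 ratio of GR1009 over GR1008 (vertical axis) against the mean normalized count of both libraries (horizontal log axis), 1 point per gene for the 2134 compared genes. The 13 polysaccharide genes lie apart at the bottom, where the ratios of genes with 0 counts depend on the pseudocount of 0.5, while 1947 genes lie between the dotted 2-fold lines.

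The polysaccharide locus ran from JYQ65_00485 to JYQ65_00545, positions 114264 to 126153 of the chromosome (11890 bp). All 13 genes were transcribed in GR1008, with 119 to 6602 counts each, and 11 of them had 0 counts in GR1009. Summed over the locus, GR1009 had 4 counts (95% Poisson interval 1.09 to 10.2) where 27849 would stand at the GR1008 level, a 6962-fold lower value (95% interval 2719 to 25555). The most transcribed gene, the exopolysaccharide biosynthesis gene JYQ65_00490 (115269 to 116039), had 6602 counts in GR1008 and 0 in GR1009, at least 3116-fold lower. A second exopolysaccharide biosynthesis gene, JYQ65_00500 (116823 to 117593), was at least 1209-fold lower. Between them lies JYQ65_00495 (116056 to 116796), a tyrosine kinase of the CpsD/CapB family, which regulates the polymerization and export of capsular and extracellular polysaccharides in Gram-positive bacteria. It had 2503 counts in GR1008 and 3 in GR1009, 1181-fold lower (404 to 5732). JYQ65_00485 at the start of the locus, without a product description, had 2582 counts against 0, at least 1219-fold lower.

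Most other genes of the locus are annotated as enzymes that make, join or modify sugars. GDP-mannose 4,6-dehydratase (JYQ65_00505), which forms a nucleotide sugar precursor, had 1795 counts in GR1008 and 0 in GR1009, at least 847-fold lower. The polyprenyl glycosylphosphotransferase JYQ65_00510, the kind of enzyme that places the first sugar on the lipid carrier, had 168 counts against 1, 238-fold lower (42.1 to 9451). Glycosyltransferases JYQ65_00515, JYQ65_00525 and JYQ65_00535 had 387, 163 and 514 counts in GR1008 and 0 in GR1009. The polysaccharide pyruvyl transferase JYQ65_00520, the hypothetical gene JYQ65_00530, the polysaccharide biosynthesis gene JYQ65_00540 and the EpsG family gene JYQ65_00545 had 457, 119, 1246 and 572 counts in GR1008 and 0 in GR1009. Their folds were at least 56.2 for JYQ65_00530, at least 76.9 for JYQ65_00525 and at least 588 for JYQ65_00540.

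The difference ended sharply at the start of the locus, whereas its end is less certain because a transposase gene follows. IMP dehydrogenase (JYQ65_00480), the gene before the locus, had a log2 ratio of -0.15, which total count scaling would turn above 0. Directly after the locus, the IS256 family transposase JYQ65_00550 (126327 to 127514) had 107 counts in GR1008 and 10 in GR1009, a log2 ratio of -3.84 (-5.02 to -2.99). This value is uncertain because same-length copies of the gene may share its reads. Whether their sequences are alike was not checked. Further on, the glycosyltransferase JYQ65_00555 stood at 0.84 with 29 and 74 counts, and the DUF1919 gene JYQ65_00565 at 1.47 (1.11 to 1.86) with 76 and 300 counts. The glycosyltransferases JYQ65_00580 and JYQ65_00610 had log2 ratios of 0.19 and 0.23. No other gene among the 1780 with at least 100 counts in GR1008 was at or below 3 counts in GR1009. Apart from the locus and JYQ65_00550, the lowest log2 ratio of any gene with at least 50 counts was -2.21, in the hypothetical gene JYQ65_06920.

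**Figure D2:**
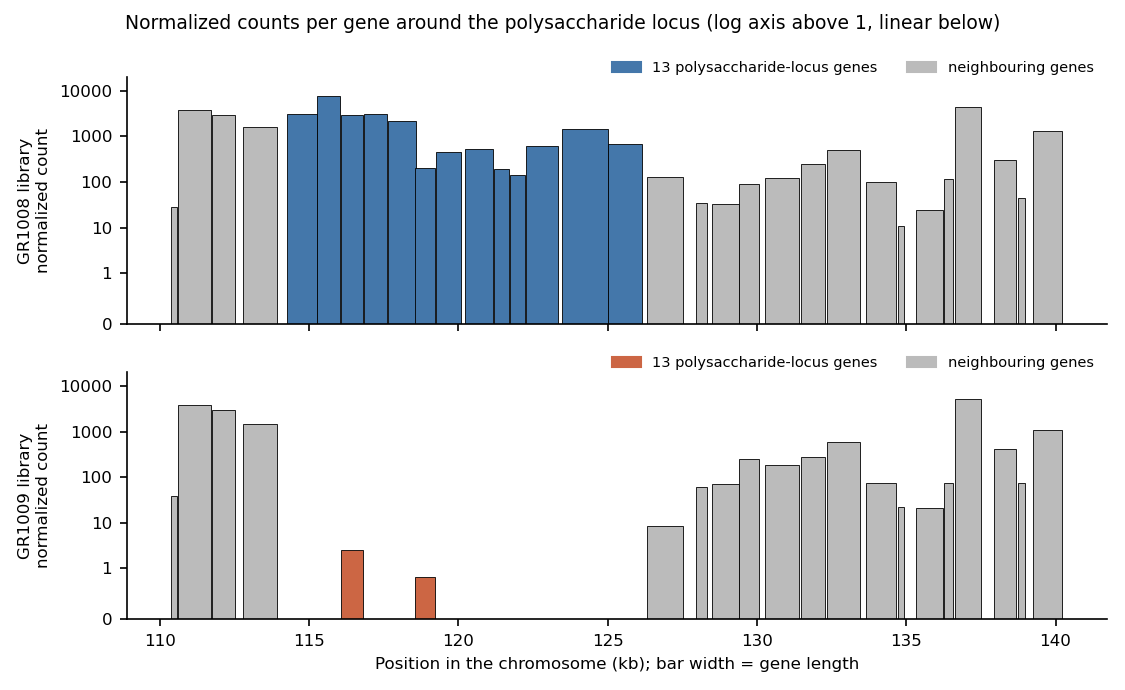
Normalized count per gene (vertical axis, log above 1 and linear below) by position in kb around the polysaccharide locus, GR1008 above and GR1009 below, with bar width showing gene length. The 13 locus genes are coloured; in GR1009 the library shows bars for JYQ65_00495 and JYQ65_00510 alone (3 and 1 raw counts), while the grey neighbours have counts in both libraries, apart from 1 transposase gene at 0 in both.

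Other polysaccharide genes did not share this difference. The list of polysaccharide synthesis genes and glycosyltransferases had 31 members, of which 8 were at least 2-fold lower, all within the locus, and none was at least 2-fold higher. Its median log2 ratio was 0.09 (percentile 83.5 of matched random lists, and 0.09 with genes at 0 counts set to their bound), whereas its mean was -2.54, so median and mean differ in sign. UDP-galactopyranose mutase glf was at 0.50, the lipopolysaccharide biosynthesis gene JYQ65_08655 at 0.94, and UTP-glucose-1-phosphate uridylyltransferase galU, which supplies UDP-glucose, at 0.01.

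In the opposite direction, 1 gene was near 0 in GR1008. The IS256 family transposase JYQ65_10745 (2104982 to 2106169) had 3 counts in GR1008 and 276 in GR1009, 65.0-fold higher (22.0 to 317). It is 1 of 13 IS256 genes of 1188 bp in the table. These may share reads if their sequences are alike, which was not checked, so its value is uncertain. Summed over these 13 genes the log2 ratio was -0.07 (-0.19 to 0.06), above 0 under total count scaling, and it depended on single copies, at -0.42 (-0.55 to -0.29) without JYQ65_10745 and 0.65 (0.47 to 0.82) without JYQ65_05850. Transposase and insertion element genes as a list (168 compared of 209) had a median log2 ratio of 0.06, at percentile 40.4, with 25 members at least 2-fold higher and 17 at least 2-fold lower. The single run of higher genes, JYQ65_00850 to JYQ65_00860, consisted of transposases. They had 0, 138 and 0 counts in GR1008 and 24, 422 and 18 in GR1009. Shuffles of the gene order gave a median of 0 such runs and at most 2. The share of shuffles with such a run was not counted, so this cannot decide whether the run is within chance. Without transposases and insertion elements 41 genes were at least 2-fold higher in GR1009.

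Ribosomal protein genes stood higher in GR1009. Of 56 compared ribosomal protein genes, 53 had a log2 ratio above 0, and their median of 0.45 exceeded those of all 10000 matched random lists. At least 2-fold higher were rpmI, for ribosomal protein L35, at 1.52 (1.25 to 1.80), and a low-count copy of rpmG. Ribosomal protein S8 (rpsH) was at 0.99 (0.85 to 1.13) and the type B L31 gene JYQ65_01270 at 0.93 (0.66 to 1.21). Another rpmG copy, with 7 and 3 counts, was the 1 member at least 2-fold lower. Of 22 aminoacyl-tRNA synthetase genes, which charge tRNAs with amino acids, 17 lay above 0. Their median was 0.20 at percentile 99.5, or percentile 95.6 when the list was shifted along the gene order instead, which no longer lies in the upper 2.5%. Lysyl-tRNA synthetase lysS was at 0.44 (0.40 to 0.49), tyrosyl-tRNA synthetase JYQ65_00395 at 0.35 and valyl-tRNA synthetase JYQ65_02835 at 0.34. Elongation factor Tu (tuf), among the most abundant transcripts, was at 0.31 (0.31 to 0.32).

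Genes for peptide and amino acid uptake and peptidases were also higher as a list, with 41 of 54 members above 0 and a median of 0.18 at percentile 99.8. At least 2-fold higher were the amino acid ABC transporter permease JYQ65_05015, at 1.40 (0.67 to 2.23), and brnQ, a branched-chain amino acid carrier with 6 and 27 counts, and at least 2-fold lower was the peptidase gene JYQ65_04865 with 17 and 5 counts. The D-alanyl-D-alanine carboxypeptidase JYQ65_09930, a cell wall enzyme that the list holds by its name, was at 0.63 (0.48 to 0.79), and the L,D-transpeptidase JYQ65_08180, likewise a cell wall enzyme, at -0.67 (-0.73 to -0.60). CRISPR-Cas and restriction-modification genes, which act against foreign DNA, had a median of 0.39 at percentile 99.9, with 14 of 15 members above 0. The 15 members lay in only 5 runs of adjacent genes, and the percentile was 98.0 when the list was shifted along the gene order. Examples are casA of the type I-E system (JYQ65_07525) at 0.62 (0.50 to 0.74), cas1 of the type II system at 0.68 (0.23 to 1.16) and the restriction specificity subunit JYQ65_09025 at 1.25 (0.67 to 1.89), which was the 1 member at least 2-fold higher.

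Pyrimidine synthesis was the list with the lowest median, -0.49 over 14 genes (-0.19 under total count scaling), at percentile 0.23. The interval of this median over genes, -1.15 to 0.03, spans both signs. At least 2-fold lower were 5 members, of which carA and JYQ65_07385 stayed so under total count scaling. These were carA at -1.34 (-1.36 to -1.32) and carB (JYQ65_07390) at -1.15 (-1.17 to -1.14), for carbamoyl phosphate synthase, dihydroorotate dehydrogenase (JYQ65_07385) at -1.31 (-1.34 to -1.28), dihydroorotase (JYQ65_07400) at -1.06, and orotate phosphoribosyltransferase (JYQ65_00285) at -1.05. The first 4 of these are adjacent (1453714 to 1460196), and with 1 value per run of neighbouring members the median was -0.08, which total count scaling would turn above 0, as it would the -0.21 of a second carB copy, JYQ65_04490. The genes for CTP synthase (JYQ65_01260) and uracil phosphoribosyltransferase upp, of later and salvage steps, were at 0.02 and 0.03. Cytosine deaminase codA and the cytosine permease JYQ65_05590 beside it, which take up and use cytosine, were at -1.47 (-1.54 to -1.40) and -1.35 (-1.43 to -1.28). Purine synthesis had a median of -0.18 (percentile 7.88), which total count scaling turns above 0 and which was 0.25 with 1 value per run, with the low-count purS at -1.39 (-2.63 to -0.32), purD at -0.53 and purE at -0.49 against 0.86 for the adenylosuccinate lyase JYQ65_05030.

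**Figure D3:**
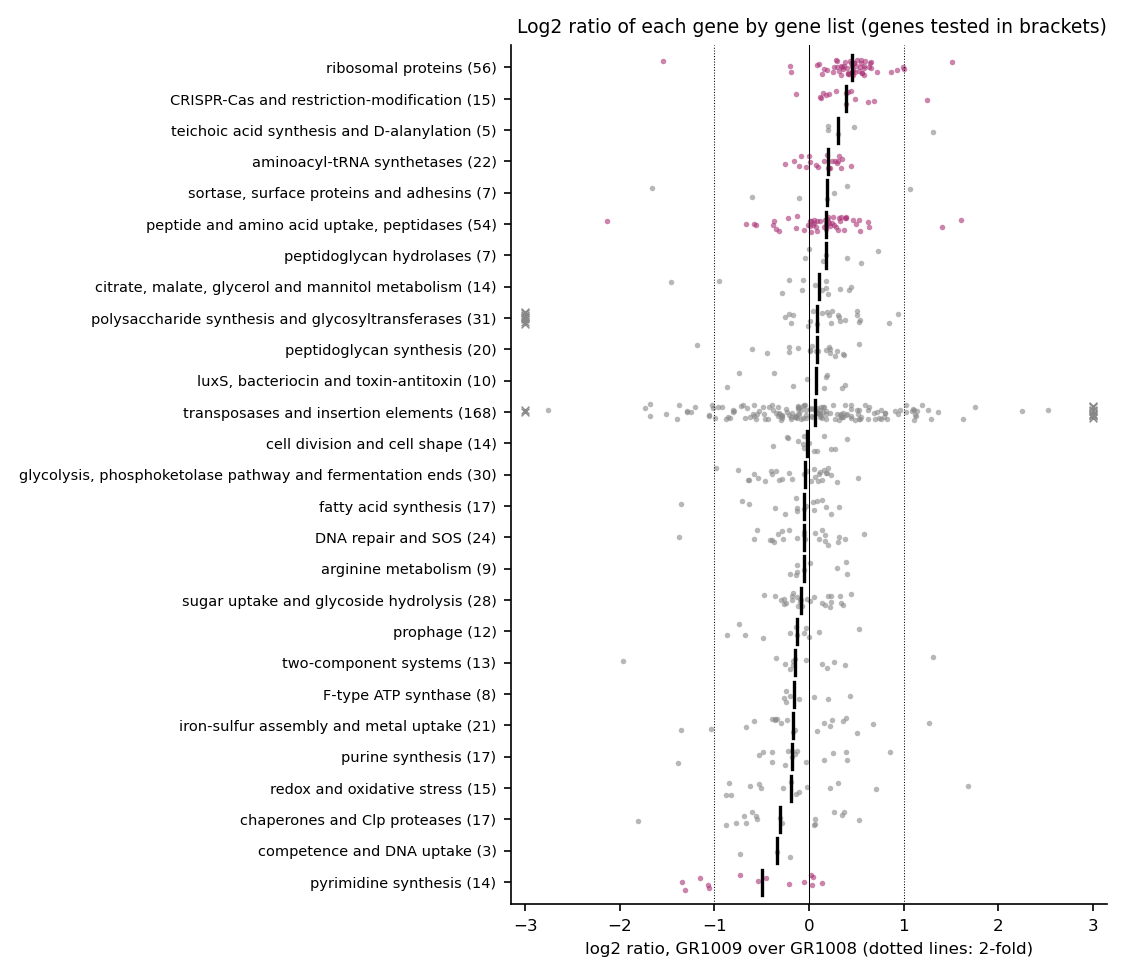
Log2 ratio of GR1009 over GR1008 (horizontal axis) for each gene of 27 lists, 1 point per gene, with black bars at the list medians. Magenta lists had medians in the outer 2.5% of matched random lists on either side; crosses at the edges are genes beyond 3 in either direction, such as the 8 polysaccharide genes on the left.

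Among chaperone and Clp protease genes (17 compared), the median was -0.31 at percentile 4.05, and -0.00 under total count scaling. With 1 value per run of neighbouring members it was -0.05. The Clp ATPase subunit JYQ65_00195 was at -1.81 (-1.82 to -1.80). Its 694268 counts in GR1008, not corrected for gene length, were the second highest there. The heat shock genes dnaJ, groL, hrcA and dnaK were at -0.88, -0.77, -0.69 and -0.66, whereas clpP (JYQ65_02170) and trigger factor (JYQ65_03580) were at 0.53 and 0.37. Redox and oxidative stress genes had a median of -0.19 (percentile 15.6), above 0 under total count scaling. Thioredoxin trxA (JYQ65_02995) was at -0.88, methionine sulfoxide reductase msrB at -0.85 and the Dyp-type peroxidase JYQ65_02400 at -0.82, against 0.71 for thiol peroxidase tpx and 1.68 for the low-count glutaredoxin gene nrdH, with 5 and 24 counts.

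Lower genes lay in 7 runs of at least 3 neighbours (38 genes), against at most 3 runs in 1000 shuffles. The shuffles also part neighbours that may be transcribed together, so they cannot show that this number of runs is particular to GR1009. After the polysaccharide locus, the longest were 2 runs of 5 genes. From 1021953 to 1023698, amaP (-1.15), the DUF2273 gene JYQ65_05195 (-1.49), the Asp23/Gls24 gene JYQ65_05200 (-1.14), the GlsB family gene JYQ65_05205 (-1.51) and the hypothetical gene JYQ65_05210 (-1.09) were lower; Asp23 and AmaP are membrane-associated alkaline shock proteins. From 1145346 to 1149392, a zinc-binding dehydrogenase (JYQ65_05800, -1.59) and the parts of an ABC transporter with a glycine betaine substrate-binding protein (JYQ65_05805 to JYQ65_05820, -1.69 to -1.03) were lower. Glycine betaine is a compatible solute. This second run lies in the window from 1.1 to 1.2 Mb, in which many genes were lower and which is weighed below. Under total count scaling 3 runs were left, the polysaccharide locus, JYQ65_05800 to JYQ65_05815 and JYQ65_06915 to JYQ65_06930.

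The transcripts with the most counts included many of central metabolism. Phosphoketolase (JYQ65_10825), the key enzyme of heterolactic fermentation, had the most counts in both libraries, 968215 in GR1008 and 1097906 in GR1009. Counts are not corrected for length, so this gene of 2400 bp need not lead per base. Its log2 ratio was -0.32 (-0.32 to -0.32). Lipoate-protein ligase (JYQ65_06935), dihydrolipoyl dehydrogenase lpdA and pyruvate dehydrogenase subunit pdhA, which lie together, were at -0.81, -1.06 and -0.49. Glyceraldehyde-3-phosphate dehydrogenase gap was at 0.18, and the transfer-messenger RNA ssrA, which rescues stalled ribosomes, at -1.17 (-1.18 to -1.17). Glycolysis, phosphoketolase pathway and fermentation end genes as a list had a median of -0.04 (percentile 60.7), with the L-lactate dehydrogenase JYQ65_03430 at -0.98 (-1.04 to -0.92). The F-type ATP synthase genes had a median of -0.16 (percentile 27.1), sugar uptake and glycoside hydrolysis genes -0.08 (percentile 32.7), and arginine metabolism -0.06 (percentile 48.7). These 4 medians turn above 0 under total count scaling. Within them, arginine deiminase arcA and carbamate kinase arcC were at 0.39 and 0.40 and the sucrose-6-phosphate hydrolase JYQ65_09890 at 0.44, against -0.48 for the beta-galactosidase small subunit JYQ65_01545. Citrate, malate, glycerol and mannitol genes had a median of 0.10 (percentile 84.6), or -0.07 with 1 value per run of neighbouring members, with citrate lyase subunit citE at 0.45 and isocitrate dehydrogenase icd at -1.46 (-1.75 to -1.18).

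Lists of genes that set cell shape and build the envelope had medians inside the central range of matched random lists. None of 14 cell division and cell shape genes reached 2-fold, and their median was -0.03 (percentile 51.2), above 0 under total count scaling and with 1 value per run. Their widest values were 0.40 for the cell division gene JYQ65_03330, 0.28 for gpsB and -0.38 for ftsY, and the septal ring gene ftsZ was at -0.22, which total count scaling would likewise turn above 0. Peptidoglycan synthesis had a median of 0.08 (percentile 86.2), with the racemase family gene JYQ65_05650 at -1.19 (-1.74 to -0.67), glmS at -0.60 and the penicillin-binding protein JYQ65_08100 at 0.53, and peptidoglycan hydrolases 0.18 (percentile 88.4), with the LysM gene JYQ65_02370 at 0.73 (0.68 to 0.78). All 5 teichoic acid genes, which add D-alanine to teichoic acids, were above 0, with a median of 0.31 (percentile 94.0); dltD was at 0.31, dltC at 0.48 and dltX (JYQ65_00365) at 1.31 (0.51 to 2.23). Surface protein genes went both ways around a median of 0.19 (percentile 85.0). The LPXTG protein JYQ65_00960, of a kind that sortase links to the cell wall, had 109508 counts in GR1008 and 49016 in GR1009, at -1.66 (-1.68 to -1.65), and the serine-rich repeat adhesin JYQ65_07110 was at 1.06 (0.78 to 1.35).

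The remaining lists had medians inside the central range of matched random lists. Fatty acid synthesis was at -0.05 (percentile 36.4), with the acetyl-CoA carboxylase subunits JYQ65_01925 and JYQ65_01930 at -1.35 (-1.41 to -1.30) and -0.70. Iron-sulfur assembly and metal uptake was at -0.17 (percentile 10.1), or 0.00 with 1 value per run. The low-count ferrous iron transport gene JYQ65_06730 was at -1.04 (-1.98 to -0.17) and the SufD family gene JYQ65_08320 at -1.36 (-1.40 to -1.31). The metal ABC transporter gene JYQ65_01135 was at 1.27 (0.72 to 1.88). DNA repair and SOS was at -0.05 (percentile 44.6), with the recombination gene JYQ65_05610 at -1.38 (-1.45 to -1.30). Prophage genes were at -0.13 (percentile 16.6). Two-component systems were at -0.15 (percentile 21.0), with the response regulator JYQ65_04810 at -1.97 (-3.01 to -1.11) and the histidine kinase JYQ65_04805 beside it at 1.31 (0.19 to 2.70). These 5 medians turn above 0 under total count scaling. Competence and DNA uptake, with 3 genes, was at -0.34 (percentile 13.5), and luxS, bacteriocin and toxin-antitoxin genes were at 0.07 (percentile 60.3), or -0.01 with 1 value per run. The ribosomal and transfer RNA list had no compared gene. Single genes with a high lower bound outside the lists included moaA, of molybdenum cofactor synthesis, at 1.23 (0.97 to 1.51), the Rha family regulator JYQ65_04170 at 1.16 (1.02 to 1.30) and the abundant hypothetical gene JYQ65_07715 at 0.95 (0.91 to 0.98).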

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

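The tests on depth, near-identical copies and DNA loss for the polysaccharide genes, and both tests on the window from 1.1 to 1.2 Mb, were chosen after the result was seen, and the other 3 tests were added after the data were seen but before their own values were known.

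Counts of rRNA and tRNA genes lie outside the comparison and are listed because they exceed what a count of 0 allows in both libraries. They came to 1329 in GR1008 and 731 in GR1009 over 73 genes, of which 28 had counts. The rRNA genes gave 1095 and 379 of these and the tRNA genes 234 and 352. A single 16S rRNA gene, JYQ65_03140, held 915 of the rRNA counts in GR1008 and 259 in GR1009.

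The 13 neighbouring polysaccharide genes at 0 to 3 counts in GR1009 were weighed first. Lower depth or another scaling of the GR1009 library is argued against by 1314 other genes with GR1008 counts in the range of the 13. The lowest of them had 84 counts in GR1009, against at most 3 in the 13. Repression was set against the quietest other stretch of 13 genes, which had 2297 counts in GR1009 (2089565 to 2101985). The locus, with an upper bound of 10.2, lay below every other stretch. This cannot decide on repression, because a stretch can mix genes transcribed separately and 98 of 2280 annotated genes had 0 counts in GR1009. The 13 were also picked for at most 3 counts there. Reads lost to near-identical copies are argued against because both libraries were counted on the same gene table, so GR1008 would lose them too. The 13 genes had 19669 counts in GR1008. The rule that picked them already ensured 1300, so this follows from how they were chosen and is no separate test. What stays open is that this DNA may have been lost or replaced in GR1009, or repressed or switched off completely. The gene before the locus had a log2 ratio of -0.15 (above 0 under total count scaling). The transposase gene after the locus had -3.84, which is uncertain because same-length copies may share its reads, and their sequences were not compared. No DNA reads were analysed here.

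The higher ribosomal protein genes were weighed second. A bias by gene length is argued against, because the list median stayed above every random list matched on length and expression (percentile 100), and so is gene dosage by distance from the replication origin (percentile 100 among lists matched on distance from dnaA and expression). A difference between cultures in growth state at harvest could give the same pattern and is part of the open explanations, since 1 plate per strain cannot separate it from strain.

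The genes from 1.1 to 1.2 Mb, the 100-kb window with the lowest median of 23, were weighed last. Of 105 compared genes there, 27 were at least 2-fold lower in GR1009. They include genes named above under separate functions: the run JYQ65_05800 to JYQ65_05820, icd, JYQ65_05610 and JYQ65_05650. The median log2 ratio of the window was -0.49 (-0.84 to -0.23), against 0.10 within 100 kb of dnaA. Intervals of medians in this paragraph are over genes and treat neighbouring genes as independent, so they may be too narrow. For an even fall of gene dosage from dnaA to the far side of the chromosome, a straight line by distance was used. Drawn from the genes near dnaA to this window, it put -0.45 on the 191 genes of the adjacent windows. Their median log2 ratio was -0.0837 (-0.17 to -0.03). This cannot decide on dosage, because the line ends at the window picked for its lowest median. Its neighbours lie above the line partly by that choice. Total count scaling moves these medians up by about 0.31, which turns that of the adjacent windows above 0. Loss of the whole window from part of the GR1009 cells stays open: 16 of its genes had a counting interval wholly above a ratio of 1 and 66 wholly below, but these intervals leave out the spread between cultures. Regulation by strain or growth state may also explain the pattern and was not tested.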

How the results depend on the processing

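The alternatives without transposases, by gene length, without the 13 polysaccharide genes, and matched on length or origin distance were chosen after seeing the data. TMM scaling gave the main counts. The 66 higher and 121 lower genes became 135 and 77 under total count scaling, which contain all 66 higher and 77 of the lower genes; higher genes then made up 63.7% of those beyond 2-fold against 35.3%, and 47.1% without the 20 most abundant genes, since these settings shift the ratios upward. A 4-fold rule left 18 and 24 genes and the whole interval rule 18 and 72. With at least 100 counts in the higher library 17 genes were higher, without transposases 41, and at 300 bp or longer 43, in each case because fewer genes entered. Runs of higher genes numbered 1 in the main setting, 4 under total count scaling, 2 under upper quartile scaling, without the 20 most abundant genes and without a count filter, and 0 with at least 100 counts or with 2 genes at 4-fold. Runs of lower genes went from 7 to 3 under total count scaling and to 2 with 2 genes at 4-fold, the polysaccharide locus with JYQ65_00550 and JYQ65_06920 to JYQ65_06925. Genes at or near 0 went from 14 to 15 with the limit at 10 counts. The 5 lists in the outer 2.5% numbered 4 to 5 elsewhere, the lost one being aminoacyl-tRNA synthetases. Over 27 lists and 7 alternatives, 162 medians stayed inside the list's interval of the median over genes and 27 fell outside it. Under total count scaling 12 medians turned above 0, none of them of a list in the outer 2.5%. Of 58 named genes beyond 2-fold, 50 to 58 stayed so under each other scaling or pseudocount. The alternative for a table without counts did not apply. No paired analysis was possible because each strain has 1 library, and no library could be left out.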

Other observations

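The segments below were chosen after their values were seen, and none has a test between strains. A second stretch of surface polysaccharide genes, JYQ65_08545 to JYQ65_08670 (1667397 to 1698439), was slightly higher in GR1009 throughout. All 25 compared genes lay above 0, from 0.06 to 0.97, with a median log2 ratio of 0.47. Among 2061 other windows of as many neighbouring genes, 34 had a median as high and 9 had every gene above 0, so the stretch is not unique, and because its borders were set after the values were seen these numbers do not show that it is unusual. It contains rfbB (0.21), which makes a dTDP-sugar precursor, glf (0.50), the flippase JYQ65_08645 (0.30), the polymerase JYQ65_08660 (0.51) and the sugar transferase JYQ65_08670 (0.50).

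The Rha family regulator JYQ65_04170 lies in a stretch of mostly hypothetical genes, JYQ65_04165 to JYQ65_04230 (826316 to 834166), of which 12 of 14 lay above 0 and 5 were at least 2-fold higher, with a median of 0.73. It holds a single-stranded DNA-binding protein gene, JYQ65_04215, at 0.50 and the helix-turn-helix gene JYQ65_04220 at 1.13. In the other direction, 4 genes before the pyruvate dehydrogenase genes, JYQ65_06915 to JYQ65_06930, were lower, with log2 ratios from -2.21 to -1.76, among them LysR family regulators JYQ65_06915 (-1.99) and JYQ65_06925 (-2.14) and the lipolytic enzyme JYQ65_06930 (-1.76). A run of 3 genes from JYQ65_08840 to JYQ65_08850 ended in a multicopper oxidase gene with 183469 counts in GR1008 and 79932 in GR1009, at -1.70 (-1.71 to -1.69).

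Other abundant transcripts lower in GR1009 were the cation-transporting P-type ATPase JYQ65_10225, with 127374 and 46985 counts at -1.94 (-1.96 to -1.93), the RNase P RNA rnpB at -1.51, the oxidoreductase JYQ65_10080 at -1.46 and the regulator JYQ65_00190, next to the Clp gene JYQ65_00195, at -1.48. Across the 2134 genes, which are not independent replicates, the log2 ratio had a Spearman correlation of -0.13 with mean expression, -0.13 with distance from dnaA and -0.07 with gene length.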
